A study of Mus musculus with 12 samples.

How the data were processed

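Gene expression was measured with Affymetrix Mouse Gene 1.1 ST array strips in the nucleus accumbens of adult mice, with 250 ng of total RNA per array. Per the labels' protocols, the brain was sliced into 1-mm coronal sections and the accumbens, core and shell together, was micro-dissected between bregma +1.5 and +0.5 mm. Groups were taken from the sample titles, which name 6 control and 6 poly(I:C) offspring as biological replicates numbered 1 to 6 in each group. Litter, sex, array strip and processing day are not given in the sources used here, so no batch could be entered in a model. If several offspring shared a litter, the p-values take litter mates as independent animals.

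The authors deposited 1 value table of 35556 rows, with 1 log2 value per row and array. Per the submitters' processing notes, the values were made with RMA and Partek 6.6. RMA corrects the background, applies quantile normalization to the probes and summarises each probe set by median polish on the log2 scale. The RMA settings, the statistical model and the genome build are not given in the sources used here, so no coordinates are reported. The scale was read from the values, which ran from 1.86 to 12.29 with array medians from 4.78 to 4.85. Because RMA pulls the arrays to a common distribution, a change shared by most transcripts would not be visible, and small differences in low values are compressed. For arrays the number of arrays limits the precision, and no counting depth applies.

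Rows were named from the platform annotation given with the table. There were 21218 rows with 1 gene symbol (18820 different symbols), 1881 with several and 12457 with no listed gene, and only the first kind was tested. Of the 21218 symbols, 21185 were matched by gene identifier to the RefSeq gene table of GRCm38.p6, which changed 0 of them. A row is called a probe here. Where several probes carried 1 symbol, gene lists used the probe with the highest mean over the 12 arrays.

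All tests used R 4.3.3 and limma 3.58.1. Each probe was fitted with lmFit and eBayes at default settings with the exposure group as the only term, with 10 residual degrees of freedom and 3.94 prior degrees of freedom. Tests were two-sided, and Benjamini-Hochberg adjustment ran over all 21218 probes with a threshold of 0.05. No further normalization and no intensity filter were applied. Differences are poly(I:C) minus control on the log2 scale, group values are means ± SD over 6 arrays, and intervals are 95% intervals of the limma fit.

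The analysis used 33 gene lists of cell types, transmitter systems and pathways. Of these, 31 had at least 5 measured genes and were tested with fry, whose directional p asks whether the members move one way on balance and whose mixed p asks whether they change in either direction. Each kind was adjusted over the 31 lists, and the directional p was the main test. Members of a list were also adjusted over the list alone. That adjustment does not cover the number of lists, so a call made on it is weaker than a call over all genes. The haemoglobin and erythroid list had 2 measured genes and the sex-linked list 4, and neither was tested as a list. The separation of the groups was measured as the share of the total sum of squares between group means, with an exact permutation test over all 462 splits of the 12 arrays into 6 and 6.

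Genes are named by a rule. Part (a) takes, in each direction, the 10 genes with the largest difference among probes past the adjusted threshold, filled up with the smallest unadjusted p where fewer passed. It leaves out unnamed gene models, small RNA genes, olfactory, vomeronasal and taste receptors, and probes whose brighter group mean lay under the median level of 5.47. Part (b) takes up to 3 members of each list with the smallest unadjusted p. Part (c) always includes Mobp, Drd1, Drd2, Tac1, Penk, Gfap, Aif1, Bdnf and Th, as well as Mbp, which was not among the probes with 1 symbol. Its other members are not reported here. Snora3, Snora16a, Mrpl32 and BC005624 fall outside the rule and were chosen after their values were seen.

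The test was checked on simulated data with the means and spreads of the 21218 real probes and 200 changed probes. For the poly(I:C) comparison it recovered 62% of probes changed by 0.25 on the log2 scale, 96% of those changed by 0.5 and 100% of those changed by 1 or 2, with 13 false calls. The simulated probes varied independently of each other, which the real probes did not, so these rates need not hold for the real arrays. In 300 simulated runs of an unshifted list of 18 correlated genes, fry gave a directional p under the threshold in 5.7% and camera with a preset correlation in 46.7%. The mixed p of fry was not checked in this way. It compares a list with no change and not with other genes, so it can pass for many lists where many genes differ.

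The groups, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. These alternatives were quantile normalization, median centring, a filter on dim probes, array weights, the replicate number as a block, other variance models, other probe sets and thresholds, other list tests and leaving out each array in turn. After the data were seen, further fits were added with the mean levels of the cortical, septal and choroid plexus lists as covariates, with the cortical list alone as a covariate, and without control 4 and control 6. Figures were drawn with matplotlib 3.10.9.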

Results

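The nucleus accumbens, a part of the ventral striatum that receives dopamine input, was profiled in adult mice exposed before birth to maternal immune activation. Pregnant C57BL/6N mice had received an intravenous injection of 5 mg/kg poly(I:C), a synthetic double-stranded RNA that mimics viral infection, or saline on gestation day 17. Their offspring went through behavioural tests and were dissected at 12 weeks of age. There were 6 arrays from poly(I:C) offspring and 6 from control offspring. Each array gave 35556 log2 values with a median between 4.78 and 4.85, pairwise correlations between arrays ran from 0.991 to 0.997, and 0 pairs of arrays were identical. The comparison addresses which transcripts of the adult accumbens differ after prenatal exposure to poly(I:C).

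Transcripts of the myelin protein gene Mobp and of the neuropeptide galanin (Gal) fell in poly(I:C) offspring, whereas 6 genes with more modest differences rose, among them Uqcrc1, which encodes a subunit of mitochondrial complex III. Mobp went from 9.00 ± 0.16 in controls to 8.49 ± 0.06 in poly(I:C) offspring (SD, n = 6 arrays per group), a log2 difference of -0.51 (95% interval -0.65 to -0.37, limma adjusted p = 0.0411), and each poly(I:C) array lay below each control array. Gal went from 6.10 ± 0.45 to 4.87 ± 0.29, a log2 difference of -1.23 (95% interval -1.63 to -0.84, limma adjusted p = 0.0433). The groups overlapped for Gal, with control 3 at 5.32 below poly(I:C) 5 at 5.41. The poly(I:C) mean of Gal lay under the median level of all tested probes, 5.47. Uqcrc1 went from 8.67 ± 0.08 to 8.99 ± 0.08, a log2 difference of 0.32 (95% interval 0.22 to 0.42, limma adjusted p = 0.0433). Of 22 alternative settings, Mobp passed the threshold in 10, Gal in 8 and Uqcrc1 in 9.

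The other genes that rose were Azin1, which encodes an antizyme inhibitor that acts on polyamine synthesis, with a log2 difference of 0.37, Ankrd45 with 0.35, Tsnax, the partner of the RNA-binding protein translin, with 0.32, Prkag2, a regulatory subunit of AMP-activated protein kinase, with 0.26, and Slc35c2 with 0.22. The other genes that fell were the linker histone gene H1f2 with a log2 difference of -0.49, Stxbp3, a syntaxin-binding protein of vesicle fusion, with -0.33, and Pdcd5 with -0.22. Mrpl32, a mitochondrial ribosomal protein gene, and BC005624 also fell, by 0.25 and 0.27 on the log2 scale. Adjusted p-values of these 10 genes ran from 0.0433 to 0.0479.

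Several genes lay just beyond the threshold. Tac2, which encodes the neurokinin B precursor, had a log2 difference of -1.22 (7.20 ± 0.58 against 5.98 ± 0.16, limma adjusted p = 0.0519), and each poly(I:C) array was below each control array. Drd3, the dopamine D3 receptor gene that is enriched in the ventral striatum, stood at 6.89 ± 0.20 in controls and 7.48 ± 0.21 in poly(I:C) offspring, a log2 difference of 0.59 (limma adjusted p = 0.0592). St3gal1, a sialyltransferase gene, had a log2 difference of 0.70 (adjusted p = 0.0519), although a further probe of the gene gave 0.03. Gtpbp1 and Myl6 had log2 differences of 0.24 and 0.22, each with an adjusted p of 0.0519. On the lower side were the vesicle gene Vamp4 with -0.40, the ribosomal protein gene Rps15 with -0.26, the macrophage gene Mpeg1 with -0.37 and the endosomal sorting gene Vps4b with -0.29, with adjusted p-values from 0.0519 to 0.0697.

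**Figure D1:**
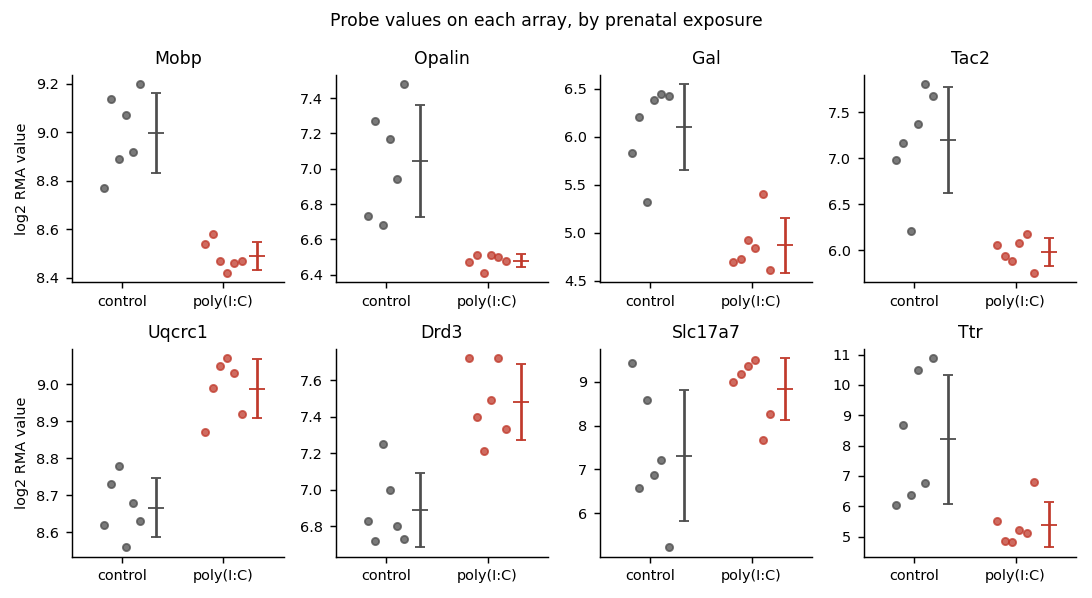
Log2 RMA values (vertical axes, a separate scale in each panel) of 8 genes on each of the 6 control and 6 poly(I:C) arrays, with points for arrays and bars for mean ± SD. Mobp lay at 8.77 or above on the control arrays and at 8.58 or below on the poly(I:C) arrays, whereas Slc17a7 and Ttr varied widely among controls.

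In all, 13 of 21218 probes passed the adjusted threshold of 0.05, 6 higher and 7 lower in poly(I:C) offspring. At an adjusted p under 0.1 there were 150 probes, 75 in each direction. An unadjusted p under 0.05 was reached by 3056 probes (14.4%, against 5% by chance), 1661 higher and 1395 lower. The ranges of the groups did not overlap for 239 probes, 1.13% of those tested, where chance gives 0.216%. The adjusted count was unstable: without control 3 it was 84, without control 1 it was 54, without poly(I:C) 6 it was 39, without poly(I:C) 1 it was 28 and without control 2 it was 6, and it was 0 without any one of control 4, control 5, control 6 or poly(I:C) 2, 3, 4 or 5. It was also 0 when the mean levels of cortical, septal and choroid plexus genes were entered as covariates (2040 at an unadjusted p under 0.05) and without both control 4 and control 6 (1768 at an unadjusted p under 0.05).

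Genes of myelin and mature oligodendrocytes, the cells that wrap axons, were lower in value in poly(I:C) offspring for 19 of the 19 measured members. Over all genes 1 of them fell (Mobp), and 13 fell when adjusted over the list alone, an adjustment that does not cover the 31 lists. Opalin, an oligodendrocyte membrane protein gene, fell on that adjustment from 7.05 ± 0.32 to 6.48 ± 0.04 (log2 difference -0.57), and Myrf, the transcription factor that drives myelin genes, from 7.56 ± 0.20 to 7.17 ± 0.06 (-0.39). Over all genes their limma adjusted p-values were 0.0820 and 0.0762. The mean over the list was 7.63 ± 0.21 in controls and 7.35 ± 0.05 in poly(I:C) offspring. The list did not pass as a directional shift (fry adjusted p = 0.120, exact permutation test of the list mean, adjusted p = 0.0895), but it passed the mixed test (fry mixed adjusted p = 0.00903). That test compares the members with no change and not with other genes, and 14.4% of all tested probes had an unadjusted p under 0.05. Without control 4 and control 6 the list-alone count was 13, and with the cortical, septal and choroid plexus means as covariates it was 7 (mixed adjusted p = 0.0377 and 0.0920). With array weights the list passed the directional test (adjusted p = 0.0435), camera with an estimated correlation gave an adjusted p of 0.493, and over the settings of that test the adjusted p ran from 0.0415 to 0.588.

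Genes of oligodendrocyte precursors, the dividing cells that give rise to myelinating cells, passed the mixed test but not the directional one (fry mixed adjusted p = 0.00102, directional adjusted p = 0.234). The mixed test asks for change in either direction and does not compare the list with other genes. Of 12 measured members 6 were higher and 6 lower in value, and 0 passed over all genes. Adjusted over the list alone, 5 fell, including Bcas1 (log2 difference -0.32), the lineage transcription factors Sox10 (-0.20) and Olig2 (-0.17), and 1 rose (Tnr). Lineage factors are not confined to precursors, so these calls do not tell precursors from mature oligodendrocytes. The list-alone counts were 2 fallen and 0 risen without control 4 and control 6, and 0 and 0 with the 3 tissue means as covariates. With a single array left out, 2 to 5 members fell, the lowest number without control 4, poly(I:C) 1 or poly(I:C) 3. The rise of Tnr ended without any one of control 1, 2 or 4 or poly(I:C) 1 to 5. The mixed adjusted p with the 3 tissue means as covariates was 0.0920.

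Other glial and vascular genes gave few calls. Of 13 microglial genes 0 passed over all genes and 2 fell when adjusted over the list alone, namely Tyrobp (log2 difference -0.19) and the complement gene C1qa (-0.16); with the 3 tissue means as covariates 0 did. The list did not pass as a directional shift (adjusted p = 0.395). The 12 astrocyte genes gave 0 calls on either adjustment, with Slc1a3 at 0.14, Slc1a2 at 0.07, Slc4a4 at -0.05 and Gfap at -0.04, and their mean (0.014), median (-0.016) and test (upward, adjusted p = 0.944) differed in sign. The 12 endothelial and pericyte genes, with Vtn at -0.11, Abcb1a at -0.07 and Flt1 at -0.06, also gave 0 calls on either adjustment. Their mean was -0.003, their median 0.020 and their test pointed downward (adjusted p = 0.944).

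Serotonin receptor genes were among the higher ones. Of 13 genes of serotonin signalling 10 were higher in value, 0 passed over all genes and 5 rose when adjusted over the list alone. These included Htr4 (6.14 ± 0.12 against 6.54 ± 0.20, log2 difference 0.40), Htr1f (0.19) and Htr1a (0.47). The mixed test passed (fry adjusted p = 0.00515) and the directional test did not (adjusted p = 0.120). The list-alone count was 1 without control 4 and control 6, 1 with the 3 tissue means as covariates, and 2 without any one of control 2, control 4 or poly(I:C) 2, 3 or 4. The mixed test did not pass without control 2 (adjusted p = 0.0779), and without control 3 the list passed the directional fry test as higher (adjusted p = 0.0415). With all arrays camera with an estimated correlation gave the list an adjusted p of 0.493.

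Marker genes of the medium spiny neurons, the main cell type of the accumbens, did not pass the directional fry test after adjustment. The 8 genes of the direct pathway were all higher in value, with Pdyn (prodynorphin) at 0.32, Chrm4 at 0.24, Tac1 at 0.24 and Drd1 at 0.17, but the list gave an adjusted fry p of 0.198 and 0 members passed on either adjustment. Camera called this list with a preset correlation (adjusted p = 0.00980) and not with an estimated correlation (adjusted p = 0.493), and fry called it without control 3 (adjusted p = 0.0450), where 2 members rose over the list alone. The 6 genes of the indirect pathway, with Gpr6 at 0.18, Sp9 at -0.06, Drd2 at -0.04 and Penk at -0.02, gave 0 calls (adjusted p = 0.944), and their mean of 0.012 stood against a median of -0.016 and a downward test. The 12 shared medium spiny neuron genes, with Arpp21 at 0.16, Gng7 at 0.12 and Gnal at 0.11, gave 0 calls on either adjustment (adjusted p = 0.944), and 1 of them rose over the list alone without control 3.

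Among 15 dopamine signalling genes 0 passed over all genes and Drd3 rose when adjusted over the list alone, whereas Maob stood at -0.24, Th at -0.20 and Drd4 at 0.09 (list adjusted p = 0.679). Drd3 aside, 1 dopamine gene fell over the list alone without control 1 or poly(I:C) 6. Of 8 genes marking the ventral and medial striatum Stard5 rose when adjusted over the list alone (log2 difference 0.75, 7.06 ± 0.29 against 7.82 ± 0.45), and Cartpt was at 0.33 and Calcr at -0.23 (list adjusted p = 0.395); the Stard5 call ended without control 4 and control 6 and with the 3 tissue means as covariates. With 1 array left out, 1 to 2 members of this list rose and 0 to 1 fell. The 14 opioid and neuropeptide genes gave 0 calls on either adjustment, with Cck, a peptide abundant in cortex, at 0.72 (list adjusted p = 0.217). Without control 3 this list passed as higher (fry adjusted p = 0.0415), and adjusted over the list alone 1 member rose without control 1 or control 3 and 2 without poly(I:C) 6. The 11 interneuron genes gave 0 calls, with Nos1 at 0.14, Kit at 0.10 and Calb2 at -0.65, and their mean of -0.030 stood against a median of 0.039 and an upward test (adjusted p = 0.305). The 17 GABA, 20 glutamate receptor and 18 synapse genes gave 0 calls on either adjustment, with list adjusted p-values of 0.564, 0.305 and 0.234. With 1 array left out the list-alone count stayed at 0 for the GABA genes, but 3 glutamate receptor genes rose without control 3 or poly(I:C) 5, and 5 synapse genes rose without control 1 or poly(I:C) 6 and 4 without control 3, where the synapse list passed as higher (fry adjusted p = 0.0415). The synapse list mean difference was 0.078 with all arrays and -0.010 with the 3 tissue means as covariates, and camera with an estimated correlation gave an adjusted p of 0.541. Examples from the GABA, glutamate receptor and synapse lists are Gabrg3 at 0.17, Gad2 at 0.16 and Gabrg1 at -0.22, Grin2a at 0.34, Grin2b at 0.22 and Grik3 at 0.21, and the synaptic vesicle genes Syn1 at 0.24 and Syn2 at 0.15 with the adhesion gene Nlgn3 at 0.16.

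Genes of tissue around the accumbens varied widely between arrays. The mean of 9 cortical glutamatergic neuron genes was 5.54 ± 0.40 in controls and 6.01 ± 0.31 in poly(I:C) offspring (fry adjusted p = 0.217). Its member Slc17a7, the vesicular glutamate transporter of cortical neurons, stood at 7.32 ± 1.49 and 8.82 ± 0.71, a log2 difference of 1.51, and Fezf2 at 0.28. Rorb rose when adjusted over the list alone (log2 difference 0.26). The mean of 11 choroid plexus and ependymal genes, from the tissue that makes cerebrospinal fluid, was 5.46 ± 0.76 in controls and 4.79 ± 0.10 in poly(I:C) offspring (adjusted p = 0.234). Ttr (transthyretin) fell when adjusted over the list alone, with 8.21 ± 2.13 against 5.38 ± 0.74, and was at 8.68, 10.48 and 10.88 in controls 2, 4 and 6. The count of choroid plexus and ependymal members that fell on that adjustment was 7 without control 1, 3 without control 5 and 2 without control 3. The Ttr call ended without any one of control 2, 4 or 6 or poly(I:C) 1 to 5, and the Rorb call without any one of poly(I:C) 1 to 4. Tmem212 was at -0.32 and Ccdc153 at -0.20. The 10 septal, pallidal and diencephalic genes, with Tcf7l2 at -0.42, Nkx2-1 at -0.13 and Gbx1 at 0.10, gave 0 calls on either adjustment (adjusted p = 0.648), and 1 of them fell over the list alone without control 3. Without control 1 the cortical list passed (fry adjusted p = 0.0424, 8 members risen when adjusted over the list alone). With all arrays camera with an estimated correlation gave the cortical list an adjusted p of 0.493.

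**Figure D2:**
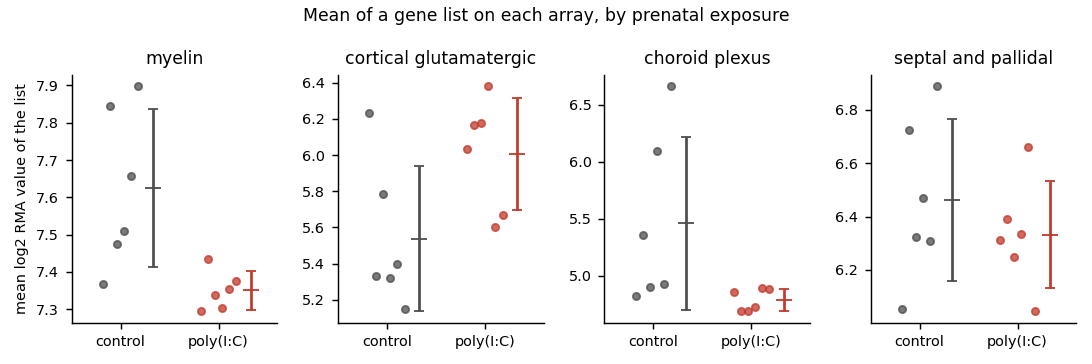
Mean log2 RMA value (vertical axes, a separate scale in each panel) of the measured genes of 4 lists on each of the 6 control and 6 poly(I:C) arrays, with points for arrays and bars for mean ± SD. The myelin mean was 7.63 ± 0.21 in controls and 7.35 ± 0.05 in poly(I:C) offspring, and the choroid plexus mean reached 6.10 and 6.67 in controls 4 and 6.

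Innate immune genes, among them sensors of double-stranded RNA, gave no call towards higher levels in the adult tissue with all arrays. Of 24 interferon response genes 19 were lower in value, 0 passed on either adjustment, and the list mean was 4.59 ± 0.03 in controls and 4.55 ± 0.02 in poly(I:C) offspring (fry adjusted p = 0.120). Ddx58 and Tlr3, which encode sensors of double-stranded RNA, were at -0.11 and -0.09, and Mx1 at -0.07. The 17 inflammatory cytokine and NF-kB genes gave 0 calls, with Tgfb1 at -0.12, Ccl2 at -0.08 and Ptgs2 at 0.26 (adjusted p = 0.385). Of 10 complement and MHC class I genes C1qa, which is also in the microglial list, fell when adjusted over the list alone, and H2-T23 was at 0.10 and Tap1 at -0.07 (adjusted p = 0.395). The C1qa call in that list ended without any one of control 2, control 5 or poly(I:C) 1, 4 or 5, and 1 member of the list rose over the list alone without any one of control 4, control 6 or poly(I:C) 2. The interferon list mean lay under the median level of all tested probes, 5.47, where arrays resolve differences poorly. So did the inflammatory list mean (4.30 in controls and 4.29 in poly(I:C) offspring). Without control 1 and without control 3 the interferon list passed as lower (fry adjusted p = 0.0424 and 0.0450), and without poly(I:C) 3 1 member fell over the list alone.

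Ribosomal protein genes were lower in value for 17 of 20 members. Over all genes 0 passed, and 5 fell when adjusted over the list alone, including Rpl4 (log2 difference -0.15), Rpl23 (-0.15) and Rps15 (-0.17, on another probe than the one given above). The mixed test passed (fry adjusted p = 0.0438), and the directional test did not (adjusted p = 0.183). The list-alone count was 1 without control 4 and control 6, 0 with the 3 tissue means as covariates, 0 without any one of control 1, control 4 or poly(I:C) 4, 9 without control 5 and 10 without control 3. The mixed test did not pass without any one of control 1, 2 or 4 or poly(I:C) 1, 3, 4 or 5, and without control 3 the list passed the directional fry test as lower (adjusted p = 0.0415). Of 23 genes of oxidative phosphorylation only Uqcrc1 rose, over all genes and over the list alone, whereas Cox7a2 was at -0.09 and Ndufs3 at 0.08 (list adjusted p = 0.736).

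**Figure D3:**
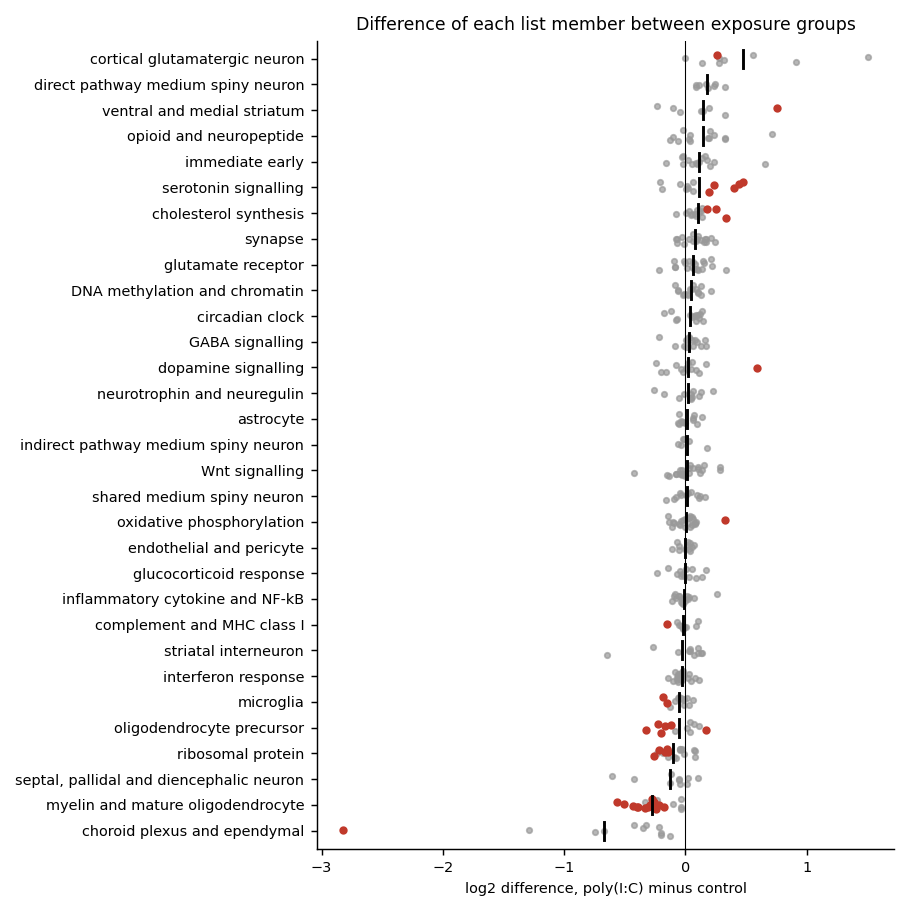
Log2 difference, poly(I:C) minus control (horizontal axis), of each measured member of the 31 tested gene lists, with red points for members that passed when adjusted over the list alone, grey points for the others and black bars for list means. The myelin list held 13 such members, and the choroid plexus list had the lowest mean at -0.671.

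Across lists, fry called 0 of 31 as directional shifts after adjustment, with 7 at an unadjusted p under 0.05, and the exact permutation test of list means called 0. Camera with a preset correlation called 8 lists (myelin, choroid plexus, ribosomal, cortical, cholesterol synthesis, synapse, direct pathway and oligodendrocyte precursor), and 0 of these calls held with an estimated correlation, where the smallest adjusted p was 0.493. Without control 3 fry called 7 lists, and without control 1 it called 3, the myelin list among them both times.

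The exposure groups as a whole stood apart by more than most other splits of the arrays. The difference between group means took 19.0% of the total sum of squares over the 21218 probes, against a median of 8.62% over all 462 splits of the arrays (exact permutation p = 0.00433). Control arrays lay 17.2 ± 3.2 log2 units from their group mean over all probes and poly(I:C) arrays 13.8 ± 3.1, a difference that did not pass an exact two-sided permutation test (p = 0.0823, 924 assignments). Without control 4 and control 6 the share was 16% (exact permutation p = 0.0619), and with 1 array left out it was 17.6% to 22.9% (exact permutation p from 0.00216 to 0.0195).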

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

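The values in this part come from a search planned before the data were examined, for an array far from the others of its group. Snora3, Snora16a, Mrpl32 and BC005624 were added to it after their values were seen. In 296 groups of 6 arrays searched, over list means and named genes, 23 had an array whose gap to its neighbour took an unusually large share of the group's range, where chance gives about 1 in 20 groups. Many of these measures share genes and arrays, and most genes were named for their p on these arrays, so that rate is only a rough guide.

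The array poly(I:C) 6 stood apart most often. Its mean over the interferon response list was the lowest of its group at 4.52 (next 4.55), and so was its mean over the inflammatory list at 4.23 (next 4.29). It was highest of its group for Ttr at 6.80 (next 5.51), Th at 6.20 (next 5.45), Pdyn at 7.23 (next 6.84), Gng7 at 10.54 (next 10.34), Myrf at 7.28 (next 7.18) and Rpl23 at 8.98 (next 8.89). It was lowest for the calretinin gene Calb2 at 6.03 (next 7.28) and for Hdac3 at 8.74 (next 8.91).

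Among other poly(I:C) arrays, array 2 was highest for the ribosomal protein list at 9.07 (next 9.03) and for Rps15 at 10.62 (next 10.56), and lowest for Tap1 at 4.46 (next 4.66). Array 3 was lowest for Opalin at 6.41 (next 6.47) and highest for Ddx58 at 5.25 (next 5.19). Array 1 was lowest for Sox10 at 6.58 (next 6.69), and array 4 was lowest for Bhlhe41 at 7.02 (next 7.14).

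Among controls, control 6 was lowest for Tac1, the substance P precursor, at 8.73 (next 9.34), and for Slc35c2 at 6.64 (next 6.72). Control 4 was lowest for the cholesterol synthesis list at 6.80 (next 7.00). Control 5 was highest for Mpeg1 at 6.24 (next 5.95), control 3 was highest for Myl6 at 8.66 (next 8.63), and control 2 was lowest for Mrpl32 at 5.28 (next 5.40).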

How the results depend on the processing

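The fits with tissue list means as covariates and the fits without control 4 and control 6 were chosen after the data were seen, and the other alternatives before. The 13 probes past the threshold in the reported analysis kept their sign in all 22 other settings (21 for Mrpl32) but passed in only 7 to 10 of them. The kept sign says little about stability. For all of them but Gal the groups did not overlap, so leaving out arrays could not change it. The count of probes was 38 with quantile normalization, 20 among probes at or above the median level, 140 with array weights, 1 with trend and robust variance (2939 at an unadjusted p under 0.05), and 3056, 361 and 150 at the looser thresholds (unadjusted p, unadjusted p with a fold of 1.2, and adjusted p under 0.1). By limma it was 0 with no variance moderation (2760 unadjusted), 0 over all 35556 probes of the table (4658), 0 with 3 tissue covariates (2040), 0 with the cortical covariate (2276) and 0 without control 4 and control 6 (1768). It ranged from 0 to 84 with 1 array left out. Fry called 1 list with array weights, camera with a preset correlation called 8, an unadjusted p under 0.05 gave 7, and leaving out 1 array gave 0 to 7. The share of variance between groups was 16% without control 4 and control 6 (exact permutation p = 0.0619). It was 17.6% to 22.9% with 1 array left out (exact permutation p from 0.00216 to 0.0195). The cause of these changes was not tested. The all-probe fit adjusts over more tests, but whether that alone gave its count of 0 was not tested either.

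With the replicate number as a block 0 probes passed (2801 unadjusted) and 0 lists passed (4 unadjusted). Deviations of same-numbered arrays correlated between -0.201 and 0.269, and 1 of 6 arrays in each group correlated best with its own number, so the numbers were not taken to pair the animals.

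Sign changes occurred in list means and genes that had not passed as shifts, and their cause was not tested, except under median centring. With quantile normalization the log2 differences became -0.006 for astrocyte, -0.005 for shared and -0.006 for indirect medium spiny neuron and -0.008 for oxidative phosphorylation genes. Median centring adds 1 constant to the difference of every probe (the median over probes went from 0.0016 to 0.0147), and by that construction alone the values became 0.010 for endothelial, 0.000 for inflammatory and 0.007 for glucocorticoid genes. Glucocorticoid genes gave 0.002 among probes at or above the median level. With array weights they became -0.005 for astrocyte, -0.031 for shared and -0.032 for indirect medium spiny neuron, -0.004 for dopamine, 0.003 for inflammatory and 0.010 for glucocorticoid genes. With the 3 tissue covariates they became 0.097 for Sp9, 0.029 for Drd2, -0.170 for Ptgs2, -0.020 for Nrg3 and -0.089 for Bdnf, and -0.028 for astrocyte, -0.010 for synapse, -0.007 for immediate early, 0.009 for complement, -0.015 for circadian, -0.067 for oxidative phosphorylation, -0.020 for cholesterol and -0.005 for neurotrophin genes. With the cortical covariate they became 0.039 for Sp9, 0.016 for Drd2, 0.047 for Gabrg1, -0.125 for Ptgs2, 0.124 for Gfap and -0.086 for Bdnf, and 0.013 for endothelial, 0.012 for interneuron, 0.076 for septal, -0.005 for synapse, 0.009 for complement, -0.007 for circadian and -0.058 for oxidative phosphorylation genes. Without control 4 and control 6 they became 0.025 for Sp9, -0.002 for astrocyte, -0.027 for shared and -0.008 for indirect medium spiny neuron and -0.007 for oxidative phosphorylation genes.

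With 1 array left out the differences ran from -0.107 to 0.005 for Drd2, -0.059 to 0.001 for Penk, -0.199 to 0.097 for Gfap, -0.033 to 0.056 for astrocyte, -0.020 to 0.011 for endothelial, -0.039 to 0.052 for shared and -0.031 to 0.041 for indirect medium spiny neuron, -0.057 to 0.003 for interneuron, -0.002 to 0.045 for dopamine, -0.006 to 0.048 for GABA, -0.008 to 0.036 for Wnt, -0.028 to 0.029 for glucocorticoid and -0.013 to 0.029 for oxidative phosphorylation genes. Signal over background limits what dim probes can show.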

Other observations

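The fits with tissue covariates, the fits without control 4 and control 6, the correlations between list means, the tests of correlation within the cortical and choroid plexus lists and the small RNA test were chosen after the results were seen.

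Of 15 cholesterol synthesis genes, which serve myelin and neurons alike, 14 were higher in value in poly(I:C) offspring. Over all genes 0 passed, and Dhcr7 (log2 difference 0.17), Hsd17b7 (0.34) and Fdft1 (0.25) rose when adjusted over the list alone, a count that ran from 0 to 6 with 1 array left out (6 without poly(I:C) 6) and was 0 with the 3 tissue means as covariates. The list did not pass as a directional shift (fry adjusted p = 0.305). Immediate early genes, which respond to neuronal activity, gave 0 calls on either adjustment, with Npas4 at 0.65, Dusp1 at 0.23 and Fos at 0.20 (15 genes, adjusted p = 0.557), and 1 of them rose over the list alone without control 3 or poly(I:C) 6.

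Lists of 14 circadian clock, 13 glucocorticoid response, 12 neurotrophin and neuregulin, 23 Wnt and 16 DNA methylation and chromatin genes also gave 0 calls on either adjustment, with fry adjusted p-values of 0.557, 0.972, 0.557, 0.725 and 0.219. With 1 array left out, 4 Wnt genes rose over the list alone without poly(I:C) 6 and 1 without control 2, 1 glucocorticoid response gene rose without control 3 and 1 fell without poly(I:C) 1, and 1 neurotrophin and neuregulin gene rose and 1 fell without control 1, whereas the circadian and chromatin lists stayed at 0. Examples are Tef at 0.15, Npas2 at 0.12 and Bhlhe41 at -0.12, Cdkn1a at 0.17, Per1 at 0.14 and Tsc22d3 at -0.23, Erbb3 at -0.26, Nrg3 at 0.23, Erbb4 at 0.13 and Bdnf at 0.04, Dkk3 at 0.28 and Dvl1 at 0.12, and Gadd45b at 0.21, Hdac3 at 0.12 and Hdac2 at -0.09. For the Wnt list the mean of 0.011 and the upward test stood against a median of -0.007. The red cell genes Alas2 (4.62 in controls and 4.58 in poly(I:C) offspring) and Slc4a1 (4.42 and 4.45) had log2 differences of -0.04 and 0.03. The sex-linked genes stood at 2.97 and 2.96 for Xist, 6.38 and 6.44 for Uty, 6.44 and 6.54 for Kdm5d (log2 difference 0.11, 95% interval 0.01 to 0.20) and 6.14 and 6.39 for Eif2s3y (0.25, 95% interval -0.10 to 0.60). On all 12 arrays Xist lay at 3.05 or below and the Y-linked Uty, Kdm5d and Eif2s3y at 5.66 or above. This is the pattern of male animals and argues against a difference in sex between the groups. Among 14338 probes with several symbols or no listed gene, limma called 0 when they were adjusted among themselves (lowest adjusted p = 0.119) and 1652 (11.5%) had an unadjusted p under 0.05.

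Regrouping the arrays bears on how far chance alone accounts for the counts. Among 100 splits into 6 and 6, the real one included, 1 had as many as 13 probes past the threshold (highest other 4), and 1 had as many as 3056 probes at an unadjusted p under 0.05 (highest other 3034, from the split that exchanges control 3 with poly(I:C) 5). For lists with an unadjusted fry p under 0.05, 4 of 100 splits had at least the real 7, and the highest other had 10. For both probe counts the share was under 0.05, so regrouping independent arrays seldom gives such counts. Litter is not known, and litter mates would not be independent animals, so chance is not excluded. For the lists the share lay too close to 0.05 for 100 drawn splits to exclude chance, and without control 4 and control 6 the count of such lists was 2.

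Over all 12 arrays the myelin mean was related to the cortical mean at r = -0.791 (permutation p = 0.00079, adjusted 0.00711 over 9 relations) and rho = -0.783 (permutation p = 0.00387, adjusted 0.0261), with r = -0.696 without the 2 farthest arrays. For the choroid plexus mean r was 0.720 (permutation p = 0.0173, adjusted 0.0389) and rho 0.755 (permutation p = 0.0058, adjusted 0.0261), with r = 0.828 without the 2 farthest. For the septal mean r was 0.697 (permutation p = 0.0124, adjusted 0.0372) and rho 0.469 (permutation p = 0.127, adjusted 0.190), and with r = 0.111 without the 2 farthest this relation rests on those arrays. These values over all arrays include the difference between the exposure groups.

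Within the 6 controls r was -0.816 for the cortical mean (exact permutation p = 0.0444, adjusted 0.0799), 0.912 for the septal mean (exact permutation p = 0.0111, adjusted 0.0372) and 0.580 for the choroid plexus mean (exact permutation p = 0.235, adjusted 0.352). The values of rho were -0.829, 0.829 and 0.829 (exact permutation p = 0.0583 and adjusted 0.105 for each), and without the 2 farthest arrays r was -0.600, 0.743 and 0.905. Within the 6 poly(I:C) arrays r was -0.215, 0.014 and -0.215 (exact permutation p = 0.700, 0.982 and 0.724, adjusted 0.814, 0.982 and 0.814). There rho was -0.314, 0.143 and -0.143 (exact permutation p = 0.564, 0.803 and 0.803, adjusted 0.725, 0.803 and 0.803), and r without the 2 farthest arrays was -0.068, 0.593 and 0.617.

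Myelin genes were lower in value on poly(I:C) arrays, and neighbouring tissue taken along in different amounts is a candidate explanation. With the cortical, septal and choroid plexus means as covariates the myelin list difference went from -0.274 (95% interval -0.473 to -0.076) to -0.167 (-0.373 to 0.038) by ordinary least squares, as for the other intervals of this part, so for this list dissection and exposure cannot be told apart, because the interval holds both 0 and the plain difference. Mobp alone went from -0.509 (-0.668 to -0.351) to -0.397 (-0.533 to -0.260). Mobp had the lowest p of all tested probes on these same arrays, so this interval cannot count against the 3 tissues as its cause. Its call ended (limma adjusted p = 0.164, range 0.00539 to 0.279 over its settings) with a smaller difference and fewer residual degrees of freedom. An effect of prenatal exposure on oligodendrocytes stays open and was not tested apart from the dissection.

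On poly(I:C) arrays the cortical mean was higher in value although the list did not pass (fry adjusted p = 0.217), Gal fell, and Tac2 was lower in value without passing, whereas choroid plexus genes were high on some control arrays. Within groups the cortical members correlated at a mean r of 0.553 and the choroid plexus members at 0.786, above the 95th percentiles of 0.135 and 0.096 over 10000 random lists, but so did 15 of the 28 other lists, the shared medium spiny neuron genes at 0.795 and the myelin genes at 0.645 among them, so for these 2 lists tissue carried along in varying amount and shared regulation cannot be told apart. The mean of Gal and Tac2 went from -1.228 (95% interval -1.727 to -0.730) to -0.958 (-1.627 to -0.290) with the 3 tissue means as covariates. Both genes were named for their differences on these same arrays, so this interval cannot count against these tissues as the cause. The Gal call ended (limma adjusted p = 0.343, range 0.00234 to 0.343 over its settings) as its difference shrank and residual degrees of freedom were lost. These tissues stay open, as do tissue outside the 3 lists and an effect of prenatal exposure, which were not tested.

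The small nucleolar RNA Snora3 was chosen after its values were seen. On 1 of its 2 probes it was at 8.68 ± 0.53 in controls and 7.10 ± 0.61 in poly(I:C) offspring (SD, n = 6, log2 difference -1.58, limma adjusted p = 0.0592). The other probe had a log2 difference of -1.62 (limma adjusted p = 0.0592), and Snora16a was at -0.71 (adjusted p = 0.0697). A lower yield of small RNA on poly(I:C) arrays could give such a difference. The median over 38 other bright small nuclear and nucleolar RNA probes was -0.393 (SD 0.389), smaller in size than -0.799, which is 50% of the Snora3 difference, but Snora3 was chosen because its difference was extreme, so this comparison cannot count against yield. Of the 38 probes, which carry 27 different symbols, 32 were lower in value. At an unadjusted p under 0.05, 21 were lower and 3 higher, where 1395 of all 21218 tested probes were lower and 1661 higher. Yield and an effect of prenatal exposure cannot be told apart here.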
